A study of Mus musculus with 15 samples.

How the data were processed

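Gene expression was measured in mouse induced pluripotent stem cells (iPSC), mouse embryonic stem cells (ESC) and mouse embryonic fibroblasts (MEF) on Illumina BeadArrays, in which each probe is a bead type carrying 1 oligonucleotide and its brightness reads the amount of labelled RNA. Per the labels, total RNA was purified on columns with a DNase step and amplified with biotin labelling by a kit for Illumina arrays, and the cells received no treatment. The 15 arrays held 3 biological replicates of each of 4 iPSC clones, 1 MEF sample and 1 sample of each of 2 ESC lines. The p-values below measure the spread between these clones, lines and replicate samples. The precision is limited by the number of arrays, above all by the single MEF array, whose spread was taken to equal that of the lines.

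The deposited table used for the main results holds, per the file headers, a non-normalized signal intensity and a detection p-value for each of 25697 probes on each array. Whether background had been subtracted was not given in the sources used here, and the lowest deposited intensity on every array lay well above 0. The detection p-value was deposited by the authors beside each intensity and compares a probe with the negative controls of its array. For 2787 probes it was printed as 0 on all 15 arrays. The series' value table, deposited by the authors as intensity on a linear scale, held the same probes and was used as an alternative. Its columns each had a median of 15, with values from -33 to 22609, and for MEF, JM8 and IDG3.2, the samples whose columns can be paired by name, they correlated with the non-normalized columns at a Pearson r of 0.992 to 0.997 across probes on the linear scale. Its scale was therefore linear and its direction that of the intensity, the values below 0 show that a background had been subtracted, no centring of genes was seen, and the normalization method that made its columns alike was not given in the sources used here. The columns of the non-normalized table name the clone and not the replicate number, so the arrays of a clone are called a, b and c here, letters that only name them.

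Probes were named from the platform annotation. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and 23963 were placed on a chromosome through the gene table of the GRCm38.p6 assembly, which was used for names, chromosomes and gene order only. The sources name no genome build, so no coordinates are given. Meg3, Rian, Mirg and Ddx3y had no named probe.

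Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential model with negative controls inferred from the detection p-values, adds an offset of 16 and applies quantile normalization, and gives log2 values. Detection was set at p below 0.01. A probe entered the comparisons of cell types if it was detected on at least 1 of the 15 arrays and the comparisons of clones if detected on at least 3 of the 12 iPSC arrays, and the probe with the highest mean over the lines stood for its gene. This left 11012 genes or unnamed probes (10132 named) and 9549 (8793 named). For the comparisons of cell types the 3 arrays of a clone were averaged, so that 4 iPSC clones, 2 ESC lines and 1 MEF sample entered a linear model with 4 residual and 4.51 prior degrees of freedom. For the comparisons of clones the 12 iPSC arrays were fitted with 1 mean per clone (8 residual and 6.08 prior degrees of freedom), and each clone was set against the mean of the other three, with an F test of any difference. Each contrast used lmFit and eBayes of limma with an intensity trend, and adjusted p-values are Benjamini-Hochberg values over all genes of the fit with a threshold of 0.05. Values given with ± are log2 changes with their standard errors unless SD is written.

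A gene undetected on all arrays of the dimmer side has only a bound there. Its fold is then given as "at least", the bright side's mean against the mean, over the dim side's arrays, of the higher of the probe's own value and the lowest normalized value among detected probes of that array. Medians of gene lists are also given with such genes at their bound.

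The 34 gene lists, the comparisons, the named-gene rule and most alternatives were fixed before the data were examined. The lists cover pluripotency, germ layers and other cell types, chromatin, cell cycle, metabolism, stress, immune response, imprinted genes, Y-linked genes and housekeeping complexes. Lists with at least 5 measured members were tested with camera of limma at its preset correlation, adjusted over the lists, and again with an estimated correlation, and the members past the threshold were also counted with p-values adjusted over the list alone. The X chromosome was tested in the same way among the chromosomes. None of the calls of a fixed list in any comparison held with an estimated correlation, and the call of the X-linked genes in clone 70 did. Genes named for a comparison were the 10 named genes with the largest rise and the 10 with the largest fall among those past the threshold, without overlap between the sides and detected on at least 1 array, then up to 4 members of each list with the largest change, passing or not, and always Pou5f1, Sox2, Klf4, Myc, Nanog, Zfp42, Cdh1, Thy1, Col1a1, Meg3, Rian, Mirg, Dlk1, Xist, Ddx3y and Eif2s3y where measured. Not every such gene is printed, and list members whose calls ended with 1 line or array left out, or within 1 signal level, were in part left out for other members.

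Closeness of a clone to an ESC line was the median, over genes at least 2 apart in log2 between that ESC line and MEF, of the clone's difference from MEF divided by the ESC line's difference, so that 0 is the MEF level and 1 the level of the ESC line. The ESC lines, with 1 array each, were compared without a test, and a list's median difference was placed among 10000 random lists of the same size matched on mean expression.

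Alternatives fixed before the data were examined were log2 values without normexp, scaling to the median of the detected probes in place of quantile normalization, the series' value table (with 16 added before log2), no detection filter, probes detected on every array, every probe on its own, eBayes without the trend, an added 2-fold threshold, arrays in place of lines as replicates, each line as its own group, the line as a random block, leaving out each line or array, the replicate number as a block and an estimated correlation. After the data were seen, 2 arrays of clone 78 with a median signal above 200 were left out, the signal level of the arrays (mean signal below or above 350) was used as a block, and each signal level was analysed alone. In the comparisons of cell types the block was fitted with each line as its own group. The p-values of those fits rest on replicate arrays within clones and not on the spread between lines. The models were tested on simulated data built from the real means and spreads, with 100 genes changed 2-fold and 100 changed 4-fold. For iPSC against MEF 5% and 55% of these were recovered with 4 false calls among 11012 genes, for ESC against MEF 0% and 40% with 6, for iPSC against ESC 18% and 92% with 5, and for clone 70 87% and 99% with 16 among 9549 genes. The simulated values were independent between genes and held no difference in signal level or background between arrays. These rates therefore do not cover the effects of such differences in the real data. Intervals of chromosome shifts are 95% bootstrap intervals over genes from 2000 draws, and genes are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.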

Results

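Gene expression profiles were recorded from 15 samples of cultured mouse cells, 1 array per sample. iPSC are body cells returned to a pluripotent state by introduced transcription factors. The series concerns a way to derive them free of the introduced genes with a pair of recombinases, enzymes that excise DNA between their target sites. Clones 48, 64, 70 and 78 were each profiled in 3 biological replicates. The samples they were set against were MEF (1 array) and the ESC lines JM8, of strain C57BL6/N, and IDG3.2, of a cross of 129S6/svEvTac with C57BL/6J (1 array each). The clones and the MEF shared a mixed C57BL/6 and 129S6 background. Clone 70 was labelled female, the other clones and both ESC lines male, and the sex of the MEF was given as unknown.

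The arrays differed in brightness in a way the groups do not explain. The mean signal was 259 to 279 on 7 arrays (the 3 of clone 48, clone 64 array c, MEF, JM8 and IDG3.2). It was 451 to 563 on 6 arrays (clone 64 arrays a and b, the 3 of clone 70 and clone 78 array a) and 987 and 995 on clone 78 arrays b and c. The first set had 10045 to 10945 detected probes, the second 11885 to 12490. Clone 78 arrays b and c, the high-background arrays below, had median signals of 498 and 511 against 110 to 140 elsewhere. They had 5545 and 5404 detected probes. Within clone 64, 690 of 12850 detected probes differed by at least 2-fold between array c and the mean of arrays a and b, against 49 between arrays a and b. Across probes this difference within clone 64 correlated with that between clones 70 and 78 and clone 48 (Pearson r 0.767, Spearman rho 0.727; probes are not independent replicates). Signal level was therefore treated as a batch, called lower-signal and higher-signal below, though whether its origin was technical was not tested. Only clone 64 has arrays at both levels. Each estimate with signal level as a block therefore rests on its array c against its arrays a and b.

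**Figure D1:**
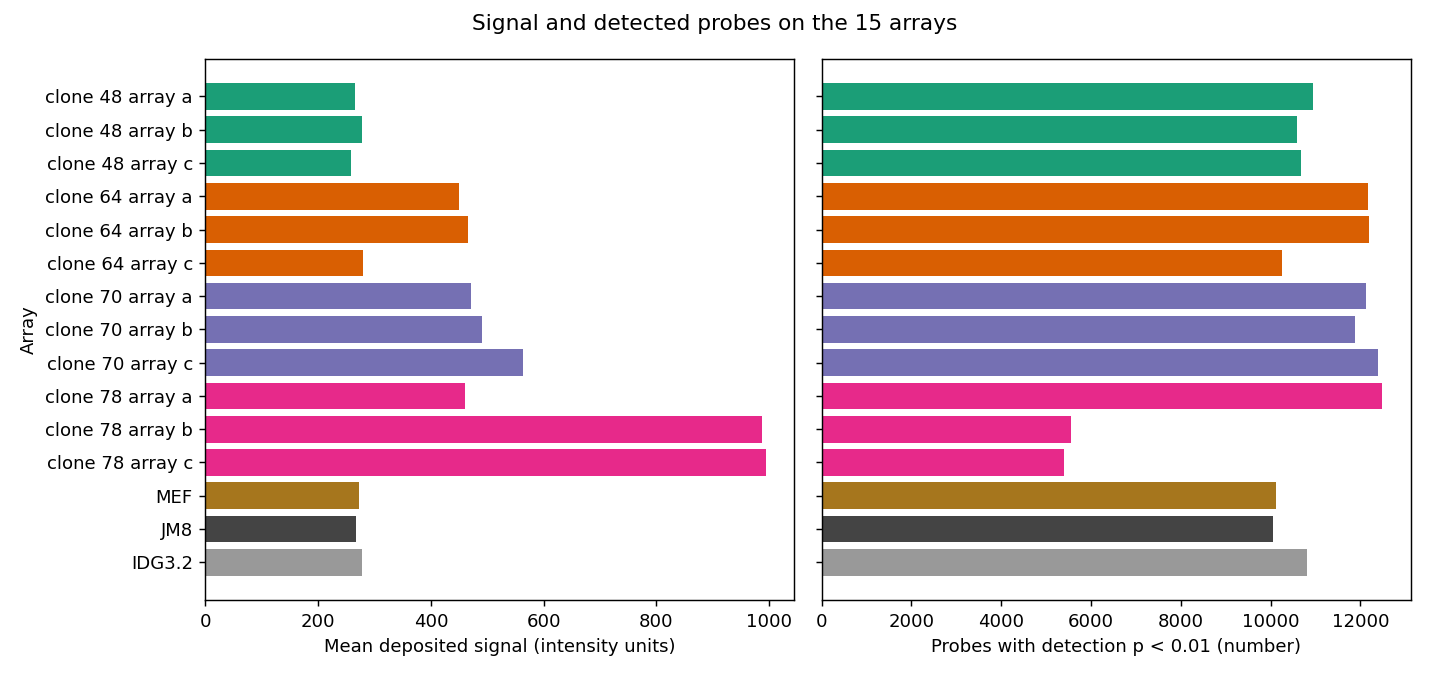
Horizontal bars give the mean deposited signal (intensity, left) and the number of probes with a detection p-value below 0.01 (right) for each of the 15 arrays. Clone 78 arrays b and c have the highest mean signals, 987 and 995, and the fewest detected probes, 5545 and 5404.

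The comparison of the 4 iPSC clones with MEF asked which genes separate reprogrammed cells from fibroblasts. Genes of the pluripotency network that were undetected in MEF were strongly expressed in every clone, and the genes of the fibroblast and its extracellular matrix were lower by large factors. Dppa5a, an RNA-binding protein of pluripotent cells, was at 14.53 ± 0.09 (log2, SD, n = 4 clones) in the clones and undetected in MEF, at least 354-fold higher (limma adjusted p = 7.76e-07). Pou5f1, the homeodomain factor also called Oct4, rose by at least 42.6-fold (4.82e-05) and Nanog by at least 56.7-fold (8.95e-05). Sox2 rose by at least 9.86-fold (0.00155) and Zfp42, a zinc finger marker of naive cells also called Rex1, by at least 27.7-fold (8.87e-05). In the other direction Col1a1, the main chain of type I collagen, fell by 5.98 ± 0.64 in log2 (adjusted p = 8.09e-04) and Thy1, a surface glycoprotein of fibroblasts, fell by 5.78 ± 1.09 (0.00772).

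In all, 1080 genes were higher and 1322 lower in the clones at an adjusted p below 0.05, 989 and 1258 of them by at least 2-fold, among 11012 tested. The other leading rises included Ooep, a maternal-effect gene of the oocyte (at least 83.3-fold), Esrrb, an orphan nuclear receptor of naive cells (at least 84.4-fold), Dppa4 (at least 68.0-fold) and Trh, which encodes thyrotropin-releasing hormone (at least 77.2-fold). Slc2a3, a glucose transporter, rose 118-fold, Bex4 by at least 72.4-fold, Gldc, an enzyme of glycine cleavage, by at least 80.2-fold, and Dnmt3l, a cofactor of de novo DNA methylation, by at least 104-fold. The leading falls were Ptn, a secreted growth factor (-7.49 ± 0.68), Actg2, a smooth muscle actin (-6.84 ± 1.59), and the lysozymes Lyz2 (-6.70 ± 0.37) and Lyz1 (-6.61 ± 0.42). Matrix genes followed, Col6a1 (-6.53 ± 0.81), Itga11, a collagen receptor (-6.47 ± 0.60), Thbs2, a thrombospondin (-6.43 ± 1.06), and Lox, the collagen cross-linking oxidase (-6.34 ± 0.96). Dlk1, a paternally expressed imprinted gene, fell by 4.19 ± 0.45 (adjusted p = 8.37e-04), and Cdh1, E-cadherin, rose by at least 23.5-fold (6.41e-05). Of the reprogramming factors Klf4 did not pass (1.01 ± 0.71, adjusted p = 0.337). Myc fell by 1.09 (0.0434), a call that ended with scaling (-1.46), within the lower-signal arrays (-1.12) and with each of the clones left out in turn (-1.14 to -1.06). Xist, the RNA that silences an X chromosome, fell by 1.37 ± 0.33 (adjusted p = 0.0192), which ended without clone 64 (-1.29). Eif2s3y, a Y-linked translation factor, gave 0.93 ± 1.87 (0.752), at 9.18, 10.15, 5.63 and 10.54 in clones 48, 64, 70 and 78. Xist was detected on 3 of 3 arrays of clone 70, labelled female, and on 0 of 3 in each clone labelled male. As the sex of the MEF was unknown, sex and cell type cannot be told apart for Xist and Eif2s3y. The call of Actg2 ended within the lower-signal arrays (-7.07). The other probes of Dppa4 gave 3.39 and 1.04 against 7.23 for the one used, and those of Itga11 -5.53 and -1.19 against -6.47. On the 12 iPSC arrays Ptn was detected on 4, Lyz2 on 2, Col6a1 on 8, Col1a1 on 6, Dlk1 on 7, Xist on 3 and Myc on 2, so their log2 differences and their order rest in part on values not above background.

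By group, 28 of 33 genes of core pluripotency rose and none fell (29 adjusted over the list alone), with a median change of 4.39, or 3.67 with bounds, and Sall4, a zinc finger factor, among the largest (at least 48.8-fold). Of the fibroblast and extracellular matrix genes 37 of 39 fell (39 adjusted over the list alone; median -4.09, with bounds -3.90). Camera called both at the preset correlation (adjusted p = 3.11e-22 and 2.77e-21) and neither otherwise (adjusted p = 0.213 and adjusted p = 0.226 with an estimated correlation). Of 18 epithelial junction and keratin genes 10 rose (11 adjusted over the list alone; median 1.95, with bounds 0.92), among them the tight junction claudins Cldn6 (at least 38.1-fold) and Cldn4 (at least 25-fold) and the splicing regulator Esrp1 (at least 21.9-fold). Of 9 genes of the DNA methylation machinery 6 rose (6 up and 1 down adjusted over the list alone; median 1.67), led by Dnmt3l and the de novo methyltransferase Dnmt3b (5.88). Camera gave these lists an adjusted p of 1.79e-06 and 2.83e-04, and an adjusted p = 0.226 and adjusted p = 0.213 with an estimated correlation. Of 13 genes of primed pluripotency and post-implantation epiblast 4 rose (4 adjusted over the list alone; median 0.61, with bounds 0.18), namely Dnmt3b (2.42 by its other probe), Otx2 (at least 7.95-fold), Pou3f1 (at least 5.61-fold) and Nodal (at least 3.81-fold; list adjusted p = 0.0129, and adjusted p = 0.531 with an estimated correlation).

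The other lists that camera called higher at the preset correlation were DNA replication, G2/M, glycolysis and ribosomal protein genes, none of them called with an estimated correlation. Of 22 DNA replication and S phase genes 17 rose (19 adjusted over the list alone; median 2.05, with bounds 1.95), such as DNA ligase 1, Lig1 (2.99), and the origin licensing factors Cdc6 (2.83) and Cdt1 (2.79), while the sliding clamp Pcna gave 3.33 without passing (adjusted p = 0.0520). Of 16 G2/M genes 9 rose (11 adjusted over the list alone; median 1.39, with bounds 1.32), with the spindle proteins Nusap1 (2.07) and Kif11 (1.91) and topoisomerase Top2a (1.73). Other probes of Lig1 gave 0.32 to 1.74, of Cdc6 0.52 and of Nusap1 0.67 and 1.53. Of 17 glycolysis genes 6 rose (8 adjusted over the list alone; median 0.87), including Slc2a3, Pdk1 (2.49) and hexokinase 2, Hk2 (1.80). The calls of the 3 lists (adjusted p = 3.18e-10, 1.79e-06 and 1.17e-04) gave adjusted p = 0.213, adjusted p = 0.226 and adjusted p = 0.249 with an estimated correlation. For ribosomal proteins 2 of 25 rose, led by Rpl4 (1.29), with 1 adjusted over the list alone and a median of 0.34 that turned to -0.25 with scaling (relative to the median of all genes 0.23 and 0.13; list adjusted p = 0.00657, and adjusted p = 0.213 with an estimated correlation).

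The other lists that camera called lower in the clones at the preset correlation were Hox, macrophage and blood, interferon-stimulated, immediate early, lysosome and unfolded protein response genes, none of them called with an estimated correlation. Of 23 Hox genes 15 fell (15 adjusted over the list alone; median -1.72, with bounds -0.90), such as Hoxc6 (-4.75), Hoxc9 (-4.07), Hoxb7 (-3.33) and Hoxa5 (-3.29). Of 8 macrophage and blood genes 7 fell (7 adjusted over the list alone; median -2.45, with bounds -1.48), with Lyz2, and the chemokine Ccl9, the complement subunit C1qb and the Fc receptor chain Fcer1g undetected in the clones and at least 4.03-fold, 3.54-fold and 3.18-fold lower. Camera called them at an adjusted p of 1.19e-08 and 3.75e-07, with adjusted p = 0.213 and adjusted p = 0.154 with an estimated correlation. Of 20 interferon-stimulated genes 11 fell (12 down and 1 up adjusted over the list alone; median -1.60, with bounds -1.42), with the deubiquitinase Usp18 (-4.83), the ubiquitin-like Isg15 (-4.35) and Ifit3 (-4.09; -2.49 and -2.77 by its other probes). Of 14 immediate early genes 8 fell (10 adjusted over the list alone; median -1.73), with Egr2 (-3.81) and Egr1 (-2.20). The call of Egr1 ended within the lower-signal arrays (-2.51). Both had an adjusted p = 0.226 with an estimated correlation against 3.50e-06 and 6.56e-06 at the preset one. Of 18 lysosome genes 6 fell (8 adjusted over the list alone; median -0.86), led by cathepsin K, Ctsk (-4.86). Of 18 genes of the unfolded protein response 5 fell (5 adjusted over the list alone; median -0.89), such as Herpud1 (-1.65). These lists had an adjusted p of 1.53e-04 and 0.00409, and adjusted p = 0.213 and adjusted p = 0.241 with an estimated correlation. Hoxc9 was detected on 6 of the 12 iPSC arrays, Hoxb7 and Ifit3 on 4 and Hoxa5, Usp18 and Ctsk on 3.

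Camera did not call the other lists in iPSC against MEF. Imprinted genes moved both ways, 5 up and 7 down of 28 (5 and 8 adjusted over the list alone), with Phlda2, a placental growth gene (at least 11.4-fold), against Dcn (-5.01) and Grb10 (-3.36). Germline genes had 2 up and 1 down of 18, with Rhox5 (5.76) and Rhox9 (at least 9.32-fold), trophoblast 1 up of 11 (Tfap2c, at least 49.1-fold), neuroectoderm 2 up and 1 down of 6 (Gbx2, 4.14), and primitive and definitive endoderm 3 up and 5 down of 17 (Apoe 4.21, Col4a1 -4.35), the same numbers as adjusted over the list alone. Targets of LIF and STAT3 had 5 up and 6 down of 18, hypoxia response 4 and 3 of 14, cell cycle inhibitors and p53 targets 1 and 3 of 20, heat shock 1 and 1 of 11 and muscle 2 and 1 of 9, and 5 and 6, 5 and 4, 4 and 6, 4 and 2 and 2 and 1 adjusted over the list alone. Endothelium had 1 and 1 of 8, mitochondrial respiratory chain 2 and 0 of 28, cholesterol biosynthesis 0 and 2 of 16 and antigen presentation 0 and 2 of 12, and 2 and 1, 0 and 0, 0 and 0, and 0 and 2 adjusted over the list alone. No gene passed among 14 of mesoderm and primitive streak and 12 two-cell-stage transcripts, over all genes or over the list alone. Lists under 5 members were not tested as sets, the 3 of neural crest and glia and 2 Y-linked genes, of which none passed, and 4 reprogramming factors, of which 2 rose and 1 fell.

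The single MEF array carries each of these contrasts. With scaling the median of all genes moved from 0.11 to -0.38 and 657 genes were called higher and 1638 lower, while among probes detected on every array 840 were higher and 322 lower. The count of 2402 became 1418 without clone 64, 3657 with signal level as a block, 5632 with the block and without the high-background arrays, and 1860 within the lower-signal arrays. The counts with the block came from fits with each line as its own group, so they do not measure the spread between lines. List medians with the block were 4.00 for pluripotency, -4.12 for fibroblast, 2.42 for epithelial, 1.78 for DNA replication, 1.29 for G2/M, 0.81 for glycolysis, 1.32 for DNA methylation, 0.61 for primed pluripotency, 0.30 for ribosomal, -1.89 for Hox, -2.50 for macrophage, -1.50 for interferon, -1.68 for immediate early, -0.85 for lysosome and -1.06 for unfolded protein genes. Within the lower-signal arrays they were 4.00, -4.12, 2.42, 1.67, 1.39, 0.77, 1.31, 0.64, 0.32, -1.75, -2.46, -1.41, -1.35, -0.88 and -0.96 in that order, and primed pluripotency was at 0.00 with scaling.

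**Figure D2:**
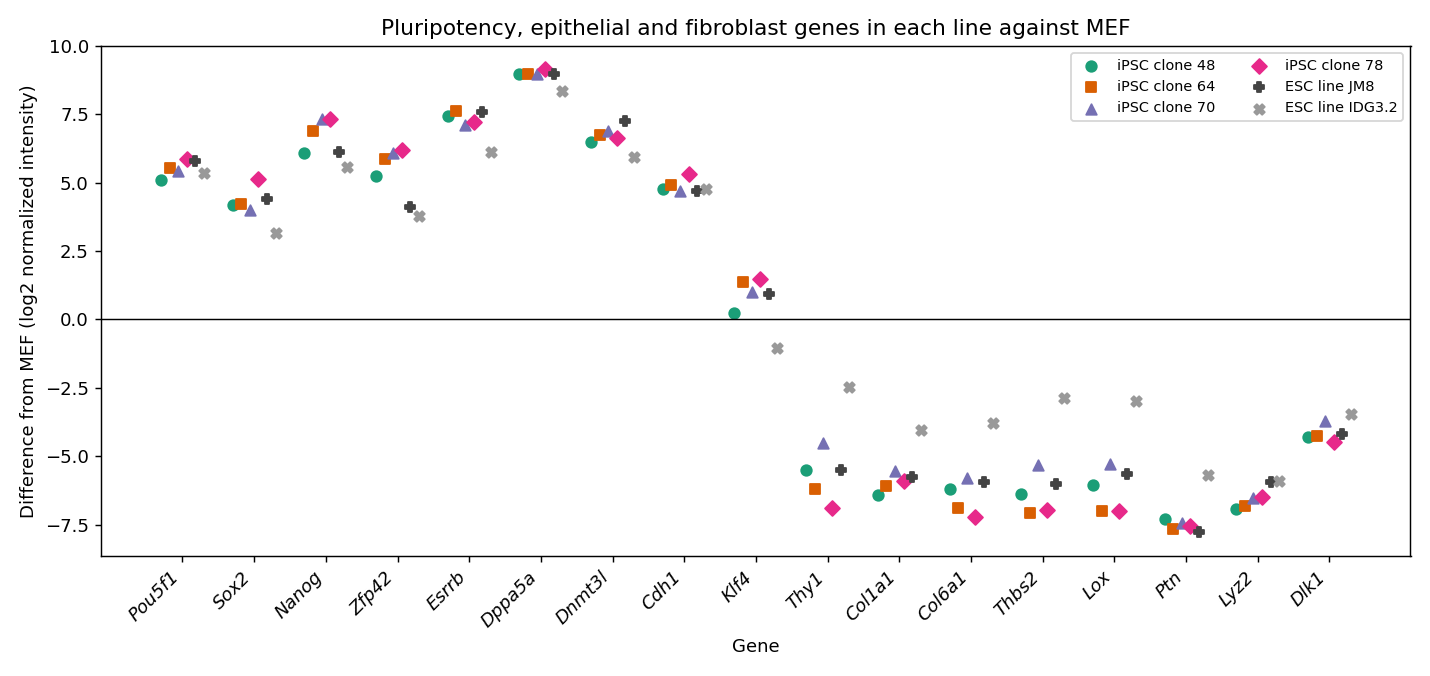
Points give, for 17 genes, the difference from MEF (log2 normalized intensity) in each of the 4 clones (mean of 3 arrays) and the 2 ESC lines (1 array each). Pluripotency genes such as Dppa5a lie above 0 and fibroblast genes such as Col6a1 below 0 in all 6 lines, with IDG3.2 closer to 0 than JM8 for Col6a1 and Thbs2.

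The ESC lines were set against the same MEF array to ask which genes mark established pluripotent lines measured alongside. Pluripotency genes were among the largest rises and matrix genes among the largest falls. Dppa5a was at least 278-fold higher in the ESC lines (limma adjusted p = 2.34e-06), Pou5f1 at least 45.3-fold (1.16e-04), Nanog at least 27.0-fold (5.64e-04), Zfp42 at least 7.44-fold (0.00127) and Sox2 at least 6.52-fold (0.00664). The other leading rises were Dppa4 (at least 62.0-fold), Esrrb (at least 60.6-fold), Trh (at least 61.8-fold), Bex4 (at least 66.7-fold) and Ooep (at least 44.7-fold). Wfdc2 rose by at least 54.1-fold, Dnmt3l by at least 97.6-fold, Gldc by at least 67.5-fold, Cdh1 by at least 20.6-fold and Slc2a3 96.5-fold. Ptn fell by 6.74 ± 0.75 in log2, Lyz2 by 5.93, Itga11 by 5.38, Lyz1 by 5.27 and Tnfrsf11b, a decoy receptor of bone turnover, by 4.94. Col1a1 fell by 4.90 ± 0.70 (0.00380), Col6a1 by 4.87 and Dlk1 by 3.83, and Ogn, a small matrix proteoglycan, was at least 18.9-fold lower. Thy1 did not pass (-3.99 ± 1.20, adjusted p = 0.0575), nor did Klf4 (-0.06 ± 0.78, 0.974) or Eif2s3y (-0.90, 0.823). Myc and Xist were each at least 1.67-fold lower (0.0484 and 0.0300), calls that ended without JM8 (-0.91 and -1.47) or clone 64 (-1.24 and -1.45), that of Xist also without IDG3.2 (-1.42) and that of Myc without any of the other clones or within the lower-signal arrays. Both ESC lines were labelled male and the sex of the MEF was unknown. For Xist and Eif2s3y sex and cell type thus cannot be told apart here either. The other probes of Ogn gave -1.42 and -1.55 against -5.17, and the other probe of Wfdc2 1.97 against 6.64. Other probes gave 2.87 and 0.08 against 7.10 for Dppa4, 2.09 against 3.79 for Sox2 and -5.02 and -1.12 against -5.38 for Itga11. Ptn, Lyz2, Tnfrsf11b and Dlk1, and Hoxc9, Usp18, Egr2 and Ctsk below, were detected on 1 of the 2 ESC arrays.

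Here 819 genes were higher and 836 lower, 771 and 811 by at least 2-fold. Camera called 15 lists, 8 higher and 7 lower, against the MEF array that the comparison of the clones also used. Of core pluripotency genes 25 of 33 rose (27 adjusted over the list alone; median 3.65, with bounds 2.88), with Sall4 at least 38.1-fold higher. Of fibroblast and extracellular matrix genes 25 of 39 fell (37 adjusted over the list alone; median -3.32, with bounds -3.13), with Col3a1 at least 14-fold lower. DNA replication genes had 14 of 22 up (19 adjusted over the list alone), with Cdt1 (2.62), Mcm2 (2.49) and Mcm7 (2.43). These lists had an adjusted p of 1.86e-20, 1.44e-19 and 8.40e-11, and adjusted p = 0.20, adjusted p = 0.21 and adjusted p = 0.20 with an estimated correlation. G2/M genes had 9 of 16 up (10 adjusted over the list alone), with Kif11 at 2.20, and epithelial genes 7 of 18 (10), with Cldn6 at least 35.3-fold higher. Glycolysis genes had 6 of 17 up (8 adjusted over the list alone), with Hk2 at 1.97, DNA methylation genes 4 of 9 (5), with Dnmt3b at 6.07 (2.38 by its other probe), and primed pluripotency genes 4 of 13 (4), with Otx2 at least 10.9-fold higher. Of 25 ribosomal proteins 1 rose (1 adjusted over the list alone), Rpl4 (1.09), a call that ended without JM8 (1.01). Hox genes had 14 of 23 down (15 adjusted over the list alone), with Hoxc9 at -4.03, and macrophage and blood genes 7 of 8 (7), with C1qb at least 3.81-fold lower. Interferon-stimulated genes had 8 of 20 down (10 down and 1 up adjusted over the list alone), with Usp18 at -5.06, and immediate early genes 5 of 14 (9), with Egr2 at -3.47. Lysosome genes had 5 of 18 down (7 adjusted over the list alone), with Ctsk at -3.98, and genes of the unfolded protein response 4 of 18 (10), with Herpud1 at -2.10. With an estimated correlation none of the 15 held (the lowest was adjusted p = 0.115, for macrophage and blood genes). Among lists camera did not call, Phlda2 (at least 27.3-fold), Tfap2c (at least 28.4-fold) and Rhox5 (4.04) rose as single genes.

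**Figure D3:**
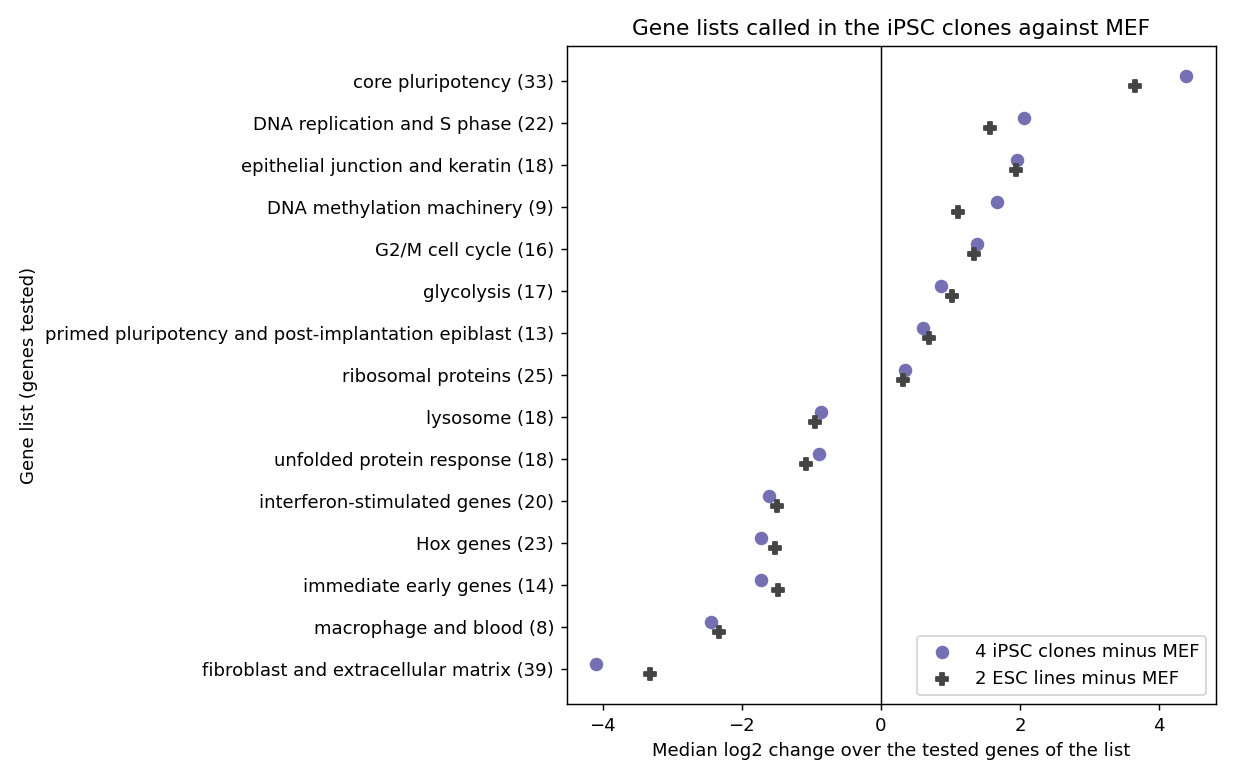
Paired points give the median log2 change of the 15 gene lists that camera called at the preset correlation, for iPSC against MEF and for ESC against MEF, which share the 1 MEF array. Pluripotency reaches 4.39 and 3.65 and fibroblast genes -4.09 and -3.32; the iPSC median of ribosomal proteins, 0.34, turns to -0.25 with scaling.

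All 3 arrays of this contrast are lower-signal, so its list medians were the same with signal level as a block. Log2 values without normexp called 648 genes higher and 1048 lower, and scaling 481 and 948, while the series' value table called 855 and 662 and probes detected on every array 655 and 188. The count of 1655 became 680 without JM8, 913 without clone 64, 2582 without the high-background arrays, 3969 with the block, 6007 with both and 1749 within the lower-signal arrays. The fits with the block took each line as its own group. Their higher counts therefore go with a spread taken from replicate arrays within clones, not with changed effects. Ccn4, a matricellular protein (-5.05, adjusted p = 0.0319), lost its call without JM8 (-3.43), without clone 70 (adjusted p = 0.0505) and within the lower-signal arrays (0.0638), and Usp18 without JM8 (-4.70).

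The iPSC clones were set against the ESC lines to ask whether reprogrammed and embryo-derived cells differ. No gene passed in limma, 0 of 11012, with a smallest adjusted p of 0.746, while 636 genes had an unadjusted p below 0.05, 405 higher in the clones and 231 lower. Pou5f1 differed by -0.09 ± 0.24, at 11.47 ± 0.31 (SD, n = 4 clones) against 11.56 ± 0.30 (SD, n = 2 lines). Cdh1 gave 0.19 ± 0.23, Sox2 0.60 ± 0.44 (the other Sox2 probe gave 2.44), Nanog 1.07 ± 0.36, Klf4 1.07 ± 0.55 and Zfp42 1.90 ± 0.30, the last with all clones above both lines and an adjusted p of 0.746. Thy1 was at -1.79 ± 0.85, Col1a1 at -1.09 ± 0.50, Dlk1 at -0.36 and Eif2s3y at 1.83, and Myc and Xist were undetected in both ESC lines, none of them passing. Other probes gave 0.12 for Pou5f1 and 0.13 and 0.30 for Klf4.

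Camera called 7 lists at the preset correlation, in none of which a single gene passed. Core pluripotency genes had 28 of 33 members higher in the clones (1 gene passing adjusted over the list alone; median 0.56, with bounds 0.51), such as Tcl1 (1.61), Tbx3 (1.59; 0.02 and 1.54 by its other probes) and the RNA-binding protein Lin28a (1.21; -0.24 by its other probe), and fibroblast genes had 33 of 39 lower (0 adjusted over the list alone; median -0.64), such as Lox (-2.03) and Thbs2 (-1.99). The median level of the fibroblast list was 6.38 in JM8 and 8.97 in IDG3.2, against 6.58, 5.82, 7.28 and 6.39 in clones 48, 64, 70 and 78, so all 4 clones lay below IDG3.2 but only clone 64 below JM8, and Thbs2 itself was at 6.78 in JM8 and 9.94 in IDG3.2. The adjusted p of the pluripotency and fibroblast lists was 1.90e-08 and 2.21e-05, and adjusted p = 0.781 and adjusted p = 0.923 with an estimated correlation. Genes of the unfolded protein response, such as the chaperone Hspa5 (1.51) and Chac1 (1.29), had a median of 0.38, and heat shock genes, such as Hsp90aa1 (2.35) and Hspb1 (1.12), 0.23 (with bounds 0.16). Trophoblast genes, such as Krt8 (0.87), Tfap2c (0.79) and Gata3, undetected in both ESC lines, had a median of 0.47 (with bounds 0.31), and LIF and STAT3 targets, such as the kinases Pim3 (0.98) and Pim1 (at least 1.46-fold higher), 0.23 (with bounds 0.10). The 4 lists had adjusted p of 0.00782, 0.0101, 0.00875 and 0.0320, and each an adjusted p = 0.781 with an estimated correlation. Two-cell-stage transcripts, among them Zscan4c (1.97), Tcstv3 (at least 2.40-fold higher) and Gm428 (at least 1.67-fold), had a median of 0.36 that was 0 with bounds (adjusted p = 0.0101, and adjusted p = 0.923 with an estimated correlation). Of these 5 lists 1 gene, in heat shock, passed adjusted over the list alone.

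With signal level as a block, each line as its own group and without the high-background arrays 134 genes passed, 99 higher and 35 lower. With each line as its own group and no block 664 did (418 and 246), and 0 did in the other settings run, where 294 to 1502 had an unadjusted p below 0.05. The fits that gave 134 and 664 took their spread from replicate arrays within clones. They do not measure the spread between lines. The list medians with the block and within the lower-signal arrays were 0.42 and 0.30 for pluripotency, -0.62 and -0.66 for fibroblast, 0.22 and 0.13 for unfolded protein response, 0.13 and 0.12 for heat shock, 0.40 and 0.71 for trophoblast, 0.21 and 0.29 for LIF and STAT3, and 0.01 and -0.02 for two-cell-stage genes.

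On a scale where MEF is 0 and the ESC line is 1, the clones lay at 0.820 (clone 48), 0.933 (64), 0.874 (70) and 0.951 (78) along the 1330 genes that separate JM8 from MEF, where IDG3.2 itself lay at 0.670. Along the 711 genes that separate IDG3.2 from MEF they lay at 1.08, 1.13, 1.11 and 1.12, and JM8 at 1.12. Split by direction, genes higher in MEF than in IDG3.2 (349 genes) put the clones at 1.17, 1.28, 1.23 and 1.33, and genes higher in IDG3.2 (362) at 1.05, 1.03, 0.957 and 0.951. Both axes use the 1 MEF array, so its noise enters every value. Across 14841 probes, the Pearson r of the clones was 0.914 to 0.965 with JM8, 0.883 to 0.976 with IDG3.2 and 0.720 to 0.820 with MEF, and that of MEF was 0.770 with JM8 and 0.857 with IDG3.2. Clone 78 had the lowest r of the clones in each range. Its high-background arrays b and c gave 0.873 and 0.862 with JM8, 0.835 and 0.821 with IDG3.2 and 0.676 and 0.667 with MEF. Its array a gave 0.947, 0.937 and 0.772 in that order. The positions of clone 78 above rest on the mean of these arrays.

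Differences among the clones were examined to see how far lines made by the same approach differ. An F test called 5051 of 9549 genes. The count was 634 with signal level as a block, 1179 with the block and without the high-background arrays, 829 within the higher-signal arrays and 3207 without clone 78 array b.

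Clone 70, the clone labelled female, stood apart by its sex-linked genes. Xlr4a, an X-linked lymphocyte-regulated gene, was at 11.52 ± 0.36 (SD, n = 3 arrays) against 6.34 ± 0.65 (n = 9) in the other clones, higher by 5.18 ± 0.33 (limma adjusted p = 9.60e-07). Eif2s3y was at 5.63 ± 0.57 against 9.96 ± 0.71, and fell by 4.33 ± 0.25 (4.23e-07), though it was detected on 1 of the 3 arrays of clone 70, so the size of the fall rests in part on values not above background. Among 308 X-linked genes 163 rose and 2 fell, 88.3% lay above the median of autosomal genes, and the median shift was 0.573 (camera adjusted p = 2.08e-28, and adjusted p = 0.0181 with an estimated correlation). On log2 values without normexp the shift was 0.359. For clones 48, 64 and 78 it was -0.183, -0.216 and -0.162 in the main fit. Clone 70 is part of the mean that each of them was set against, which lowers these values. Xist was detected on 3 of 3 arrays of clone 70 and on 0 of 9 others (limma adjusted p = 0.00412). Its level in clone 70 was not above the mean lowest detected level of the other arrays, so no fold is given, and the call ended with scaling and with the block alone (adjusted p = 0.0540).

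The other leading rises in clone 70 were Fmr1nb (3.29 ± 0.24), the matrix protease Mmp3 (3.09 ± 0.47), the chemokine Ccl7 (3.02 ± 0.48), and the X-linked homeobox genes Rhox9 (2.5 ± 0.20) and Rhox6 (2.26 ± 0.23). Erich5 (2.39), Gm14685 (2.35), the meiotic cohesin Smc1b (2.34) and the interferon gamma receptor chain Ifngr2 (2.26) followed. The other 2 probes of Ifngr2 gave -0.11 and -0.10, those of Mmp3 1.65 and 1.91, and that of Fmr1nb 0.80. On arrays a, b and c of clone 70 Ccl7 was at 7.96, 9.65 and 10.33. The Mmp3 probe that gave 1.91 was at 6.03, 7.99 and 8.99 there, against a mean of 6.54 in clone 48. On the 9 arrays of the other clones Xlr4a, Mmp3, Ccl7 and Gm14685 were detected on 6 and Smc1b on 4. The leading falls were Igf2, the imprinted insulin-like growth factor 2 (-3.12 ± 0.21, 8.71-fold, adjusted p = 1.19e-06), the myelin protein Pmp22 (-2.23; -1.30 by its other probe), the imprinted Phlda2 (-2.03 ± 0.37, 0.00294), aldolase C, Aldoc (-1.86), Adssl1 (-1.78), the glutamate decarboxylase Gad1 (-1.70) and the homeobox gene Gbx2 (-1.61), and Bahcc1 and Rras were both at -1.5, with Gad1 detected on 1 of the 3 arrays of clone 70. Thy1 was 1.69 higher (0.00704), a call that ended without clone 70 array c (1.31). Pou5f1 (0.39, adjusted p = 0.0581), Nanog (0.56, 0.0541), Sox2 (0.50; -0.51 by its other probe), Zfp42 (0.31), Klf4 (-0.03), Cdh1 (-0.29), Col1a1 (0.61) and Dlk1 (0.64) did not pass.

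Of 16 germline genes 9 rose in clone 70 (13 adjusted over the list alone; median 0.84), with Rhox9, Rhox6, Stk31 (1.80) and Taf7l (1.51). The list holds X-linked genes such as Rhox9 and Rhox6, so its rise overlaps with the shift of X-linked genes. It was not tested without its X-linked members. Of 7 two-cell-stage transcripts 5 rose (7 adjusted over the list alone; median 1.5, with bounds 1.33), with Gm428 (2.24; 1.37 with the block and without the high-background arrays, where it did not pass) and Pramel7, at least 2.12-fold higher. Their camera adjusted p was 1.16e-07 and 7.55e-05, and adjusted p = 0.0615 and adjusted p = 0.331 with an estimated correlation. Of 32 fibroblast genes 13 rose (16 up and 1 down adjusted over the list alone; median 0.57), with Bgn (1.62), Thy1 and Dcn (2.24), whose call ended without clone 70 array b (2.10) or c (1.48). The list had an adjusted p of 7.55e-05, and adjusted p = 0.421 with an estimated correlation. Its members could differ between the arrays of clone 70. On arrays a, b and c Lox was at 7.49, 7.89 and 9.13 and Col6a1 at 6.09, 7.23 and 8.02, against clone 48 means of 7.40 and 6.73. Whether this holds over the whole list was not tested. Of 18 epithelial genes 9 fell (10 adjusted over the list alone; median -0.72), such as the keratins Krt18 (-1.89) and Krt19 (-1.53), neither passing within the higher-signal arrays (-1.17 and -0.52), and Cldn6 (-1.10). Of 16 glycolysis genes 7 fell (9 adjusted over the list alone; median -0.25), with Aldoc and Pdk1 (-1.01). Both lists gave an adjusted p = 0.0562 with an estimated correlation, against 2.23e-06 and 1.75e-05. Of 12 mesoderm and primitive streak genes 5 fell (6 adjusted over the list alone; median -0.83, with bounds -0.46), such as Bmp4 (-1.34) and Cdx2, at least 2.25-fold lower. Of 15 cholesterol biosynthesis genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.47), with Hmgcs1 (-0.81), Cyp51 (-0.79) and the X-linked Ebp (1.63). Their adjusted p was 7.55e-05 and 0.00560, and adjusted p = 0.127 with an estimated correlation for both. The other 4 lists called at the preset correlation were core pluripotency (5 up and 1 down of 33, and 8 and 2 adjusted over the list alone), endoderm (1 and 3 of 14, and 1 and 6), immediate early genes (0 and 1 of 10, and 0 and 1) and LIF and STAT3 targets (1 and 4 of 18, and 1 and 4). They gave adjusted p = 0.333, adjusted p = 0.331, adjusted p = 0.333 and adjusted p = 0.119 with an estimated correlation. Imprinted genes were not called (5 up and 4 down of 27; 6 and 5 adjusted over the list alone). Taf7l, Gm428 and Dcn were detected on 4 and Stk31 on 3 of the 9 arrays of the other clones, and Krt19 on 1 of the 3 of clone 70.

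In clone 70, 907 genes were higher and 624 lower. The count was 338 with signal level as a block, 1386 with the block and without the high-background arrays, 1445 within the higher-signal arrays and 2510 without the high-background arrays. It was 743, 558 and 525 without clone 70 arrays a, b and c and 3418 without clone 78 array a. With scaling the median of all genes moved from 0.02 to -0.17, and 855 genes were called higher and 1706 lower. Within the higher-signal arrays Xlr4a differed by 4.75, Eif2s3y by -4.78, Igf2 by -2.96, Rhox9 by 2.92, Fmr1nb by 2.87, Mmp3 by 2.69, Rhox6 by 2.52, Ccl7 by 2.42, Phlda2 by -2.14, Pmp22 by -2.04 and Gbx2 by -1.91, each passing there, while Bmp4 (-0.89, adjusted p = 0.0676), Gm428 (1.31) and Dcn (2.09) did not. With the block alone, beside that of Xist, the calls of Phlda2 (-1.64, adjusted p = 0.0836), Thy1 (1.85, 0.0565), Taf7l (1.31, 0.0556), Gm428 (1.63, 0.147), Dcn (2.11, 0.106), Krt19 (-1.05, 0.109) and Cyp51 (-0.65, 0.0903) ended. X-linked genes were shifted by 0.538 there and by 0.574 with the block. List medians with the block and within the higher-signal arrays were 0.68 and 0.68 for germline, 0.97 and 0.87 for two-cell-stage, 0.52 and 0.72 for fibroblast, -0.71 and -0.42 for epithelial, -0.22 and -0.26 for glycolysis, -0.43 and -0.38 for cholesterol, -0.65 and -0.20 for mesoderm and 0.08 and -0.01 for pluripotency genes, the last 2 no longer called within the higher-signal arrays (adjusted p = 0.219 and 0.563).

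**Figure D4:**
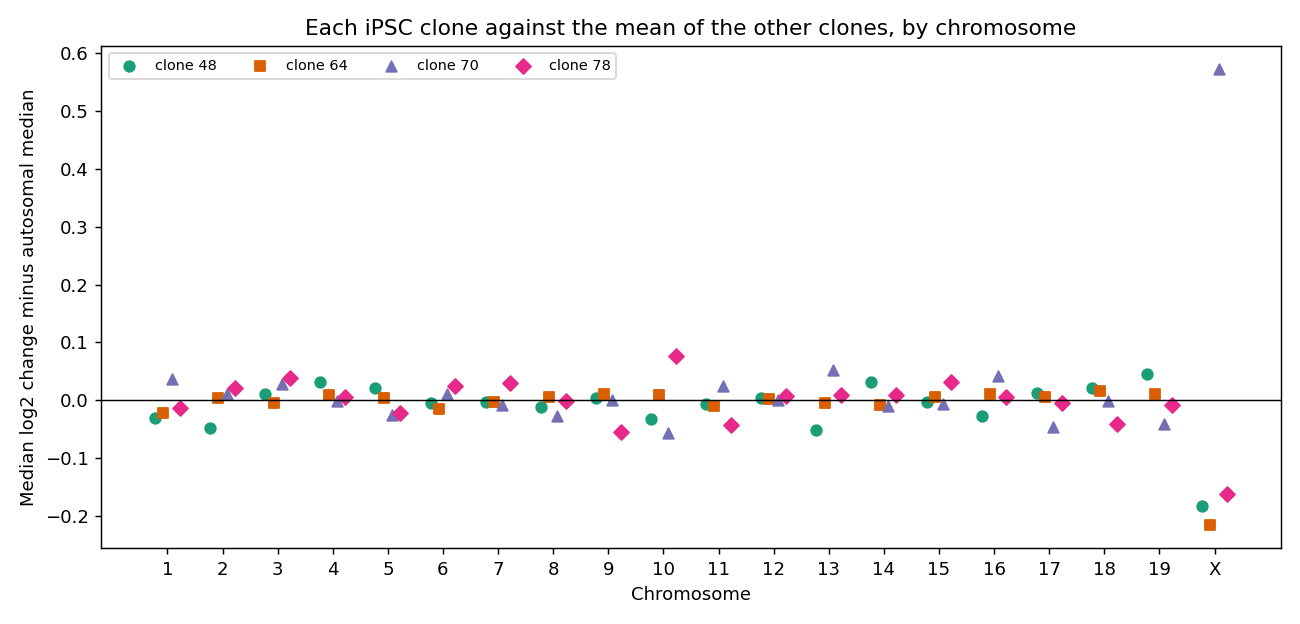
For each clone against the other clones, points give the median log2 change of the genes of each chromosome minus that of all autosomal genes. The X chromosome of clone 70 lies at 0.573, and at -0.183, -0.216 and -0.162 in clones 48, 64 and 78. Clone 70 is part of the mean that each of the other clones was set against, which lowers their X values.

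Among the clones, clone 48 was marked by genes of the primitive streak, the site where mesoderm and endoderm form in the embryo. The homeobox factor Mixl1 was at least 3.29-fold higher than in the other clones (2.68 ± 0.22 fitted, limma adjusted p = 1.12e-05) and the caudal factor Cdx2 higher by 2.67 ± 0.21 (9.62e-06). The organizer gene Gsc was higher by 2.73 ± 0.28 and the growth factor Fgf8 by 3.69 ± 0.52 (10.45 ± 0.08 against 6.76 ± 1.37, SD, n = 3 and 9 arrays). All 3 arrays of clone 48 are lower-signal and, of the other clones, only clone 64 array c shares that level, so its contrast largely coincides with that of signal levels. The arrays of MEF and the ESC lines are lower-signal too. Mixl1, Cdx2, Gsc and Fgf8 were at 5.03, 5.15, 6.21 and 4.99 in JM8 and at 5.18, 5.41, 5.11 and 5.33 in MEF. In IDG3.2 they were at 8.72, 7.11, 10.38 and 10.65, against 7.87, 8.44, 8.86 and 10.45 in clone 48. High levels of these genes were thus neither shared by all lower-signal arrays nor particular to clone 48. With the block and without the high-background arrays Mixl1 gave 2.41 (adjusted p = 0.0245), Cdx2 2.39 (0.00889) and Gsc 1.52 (0.0361), and Fgf8 1.37 without passing (0.227). With the block alone Cdx2 passed and Mixl1 (2.52), Gsc (1.71) and Fgf8 (1.89) did not. Of the 9 arrays of the other clones Cdx2 was detected on 4, Gsc and Fgf8 on 7 and Mixl1 on 0.

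Of 12 mesoderm and primitive streak genes 8 rose in clone 48 (9 adjusted over the list alone; median 1.70, with bounds 1.20), Evx1 (2.65) among them, and 5 passed with the block and without the 2 high-background arrays (median 1.45), where Evx1 did not (1.63, adjusted p = 0.0634). Of 15 interferon-stimulated genes 8 rose (8 adjusted over the list alone; median 0.37), with Usp18 (at least 2.95-fold), Isg15 (1.78) and Oasl2 (1.71), of which Usp18 also passed with the block and without the 2 arrays (2.16, adjusted p = 0.0361), though not with the block alone (2.23, 0.111), and Isg15 and Oasl2 passed in neither (0.99 for both without the 2 arrays). On the 9 arrays of the other clones Isg15 was detected on 6 and Oasl2 on 7. Of 33 pluripotency genes 19 fell (21 adjusted over the list alone; median -0.64), such as Sox2 (-2.49), Tdgf1 (-1.83) and Nanog (-1.08), and none of these 3 passed with the block and without the 2 arrays (list median -0.30, Sox2 -0.07, Nanog -0.08). The other probe of Sox2 gave -0.27 with all arrays. Camera gave these lists an adjusted p of 3.99e-05, 0.0102 and 6.04e-08, each with an adjusted p = 0.162 with an estimated correlation. Of 18 epithelial genes 8 rose (8 adjusted over the list alone), with Krt19 (2.45, against values detected on 5 of 9 arrays) and Krt18 (2.29), of 16 germline genes 9 fell (10), with Stra8 (at least 1.82-fold), and of 22 DNA replication genes 8 fell (9), with Pcna (-2.32). These 3 lists gave adjusted p of 0.0148, 2.92e-04 and 0.00559, and each an adjusted p = 0.162 with an estimated correlation. Of 7 two-cell-stage transcripts 5 fell (5 adjusted over the list alone), such as Zscan4c (-2.63; list adjusted p = 0.00685, and adjusted p = 0.332 with an estimated correlation). With the block and the 2 arrays left out these genes did not pass, at 1.56 for Krt19, 2.20 for Krt18, -0.01 for Stra8, -0.39 for Pcna and -0.40 for Zscan4c (adjusted p = 0.131, 0.149, 0.991, 0.302 and 0.890), and the list medians were 0.44 for epithelial, -0.40 for germline, -0.11 for DNA replication and -0.25 for two-cell-stage genes, against 0.52, -0.63 (with bounds -0.54), -0.21 and -1.0 (with bounds -0.36). The 6 other lists called at the preset correlation were endoderm, trophoblast, immediate early, antigen presentation and muscle genes (higher) and the unfolded protein response (lower), with adjusted p from 0.162 to 0.180 with an estimated correlation.

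The largest rises of clone 48 beside these were the interferon-induced GTPases Gbp2 (3.85 ± 0.58; 1.95 by its other probe) and Gbp2b (3.28), the Wnt target Sp5 (3.34 ± 0.63), Klhl6 (2.94 ± 0.21), Igfbp3 (2.85) and the protease Tmprss2 (2.83), of which Klhl6 was detected on 2, Tmprss2 on 4 and the others on 7 of the 9 arrays of the other clones. The largest falls were Vps4b (-2.97), Ube2c (-2.93), Cacybp (-2.87), Nono (-2.83), Slc3a2 (-2.79), Rpl22l1 (-2.76), Ddx39a (-2.72) and Stmn1 (-2.70), of which Vps4b and Ddx39a were detected on 1 and Ube2c and Slc3a2 on 2 of the 3 arrays of clone 48. With the block and the 2 arrays left out only Klhl6 (2.18, adjusted p = 0.00889) and Tmprss2 (1.71, 0.0152) of these passed, Gbp2 gave 1.69 (0.155) and Sp5 1.52 (0.364). With the block alone the call of Tmprss2 ended too (1.92, adjusted p = 0.238). In clone 48, 1970 genes were higher and 1546 lower. The count of 3516 became 7 with the block, 65 with the block and the 2 arrays left out, 2135 and 2011 without clone 48 arrays a and c, and 5306 without clone 78 array a.

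**Figure D5:**
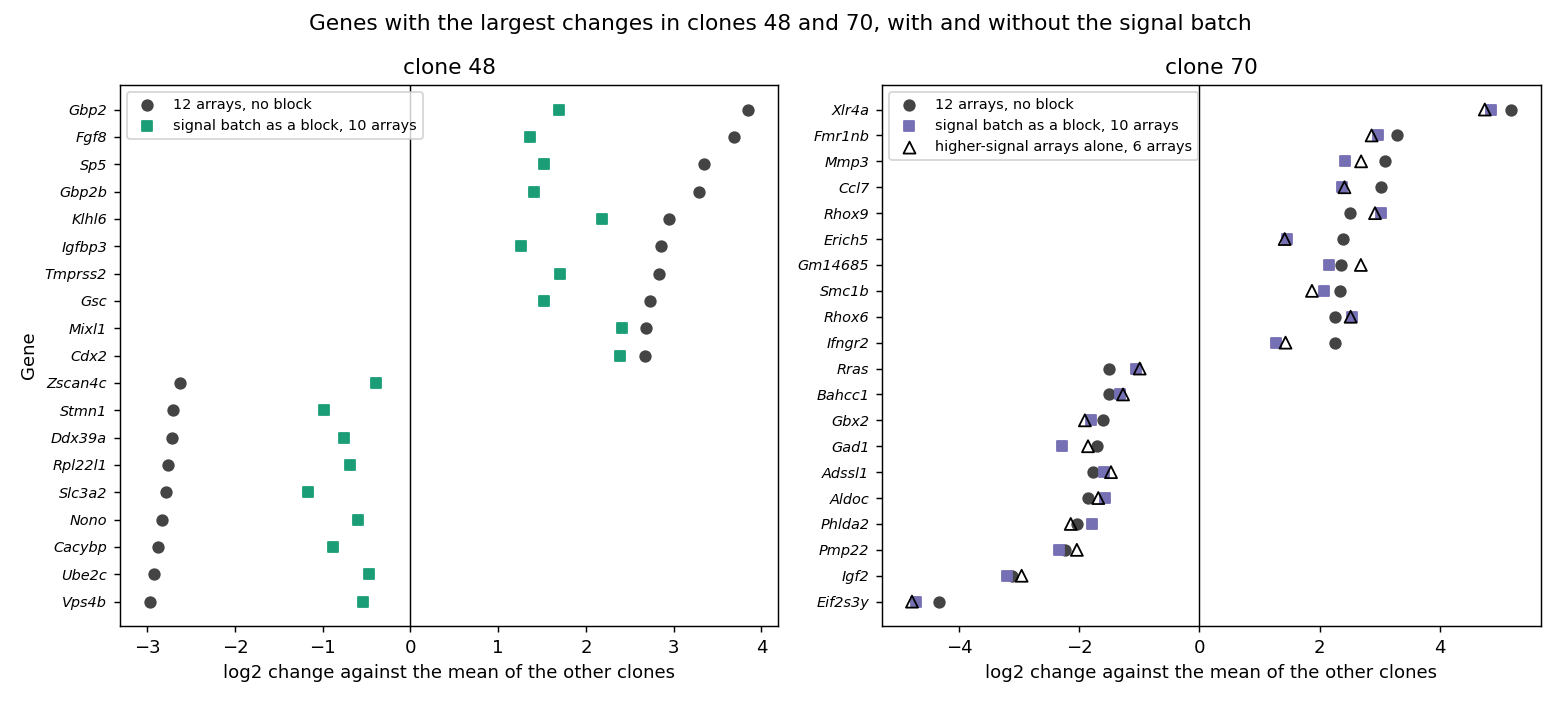
Points give the log2 change of the leading genes of clones 48 and 70 against the other clones from 12 arrays, from 10 arrays with signal level as a block and, for clone 70, from its 6 higher-signal arrays alone. The falls of clone 48 shrink with the block (Vps4b from -2.97 to -0.54), and Xlr4a (5.18, 4.85 and 4.75) and Igf2 (-3.12, -3.20 and -2.96) of clone 70 stay apart from 0.

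In clone 64 the fibroblast genes lay low as a group. Of its 32 tested members 31 were lower than in the other clones, with a median of -0.59 (with bounds -0.58), such as the proteoglycan Bgn (-1.60), Timp2 (-1.27), Fbln2 (-1.15) and Acta2 (-1.06). None passed over all genes (12 down adjusted over the list alone; camera adjusted p = 2.74e-22, and adjusted p = 0.164 with an estimated correlation). Over the 39 members tested between cell types, the median level was 6.58, 5.82, 7.28 and 6.39 in clones 48, 64, 70 and 78. The high level of clone 70 thus adds to the difference of clone 64. With the block and without the 2 high-background arrays the median was -0.74 and 4 members passed (adjusted p = 0.279 with an estimated correlation). Only 3 genes passed in limma, Eif2s3y (1.70 ± 0.25, adjusted p = 0.0318), Gbx2 (1.01 ± 0.15, 0.0318) and 1 probe without a gene name (-1.29), while 805 had an unadjusted p below 0.05. Eif2s3y was at 9.18, 10.15, 5.63 and 10.54 in clones 48, 64, 70 and 78, and Gbx2 at 10.93, 11.33, 9.36 and 10.65, so the low value of clone 70 enters the mean that clone 64 was set against, and Eif2s3y was highest in clone 78. The count was 0 with the series' value table (747 unadjusted), among probes detected on every array (399 unadjusted) and without clone 64 array a or b (504 and 545 unadjusted). It was 1 without clone 64 array c, clone 70 array b, clone 78 array c or any array of clone 48, 5 and 6 without clone 70 arrays c and a and 1163 without clone 78 array a. With the block it was 2, and with the block and the 2 arrays left out 116, where Eif2s3y gave 1.78 and Gbx2 0.83. The call of Eif2s3y ended without any array of clone 48, clone 64 array a or b, clone 70 array b or clone 78 array b or c (1.41 to 1.74). That of Gbx2 ended without any array of clone 48 or clone 64, clone 70 array b or clone 78 array c (0.97 to 1.05), and with the block alone. Glycolysis (median 0.14), mesoderm (-0.22), lysosome (-0.14), Hox (-0.09) and p53 target lists (-0.06) were also called at the preset correlation with 0 members passing (1, 1, 1, 0 and 2 adjusted over the list alone), at adjusted p = 0.164, adjusted p = 0.318, adjusted p = 0.164, adjusted p = 0.385 and adjusted p = 0.164 with an estimated correlation.

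In clone 78, which holds the 2 high-background arrays, the rises were led by Hnrnpd (at least 4.39-fold), the ribosomal protein-like Rpl22l1 (2.45), the isoprenoid enzyme Idi1 (2.44), Pcna (2.42), thioredoxin reductase Txnrd1 (2.32) and Jmjd1c (2.27). The falls were led by Wnt7b (-2.06; -0.64 by its other probe), Gm14685 (-1.97), Tceal5 (-1.83), Sphk2 (-1.77) and Selenoi (-1.71), each detected on 1 of its 3 arrays, as was Thy1. Sox2 (2.26; 1.02 by its other probe), Eif2s3y (2.22), Klf4 (0.62; 0.09 and 0.54 by its other probes), Cdh1 (0.51) and Thy1 (-1.47) also passed, the calls of Klf4 and Thy1 ending without array b (0.64 and -1.30) or c (0.49 and -1.08) and that of Sphk2 without array b (-1.45). The mean that Eif2s3y was set against holds clone 70, at 5.63. With the block the calls of these genes ended except for Gm14685 and Eif2s3y, with Hnrnpd at 2.99 (adjusted p = 0.0871), Rpl22l1 at 1.54 (0.0785), Wnt7b at -1.84 (0.0778), Sox2 at 1.21 (0.0883), Klf4 at 0.28 (0.270) and Thy1 at -1.31 (0.107), and with the block and without the 2 arrays those of Gm14685 (-1.57) and Eif2s3y (1.53) ended too. In all, 1298 genes were higher and 2716 lower, against 1684 and 1499 with scaling, which moved the median of all genes from -0.19 to 0.11, and 2082 and 2300 without the detection filter. Without arrays b and c clone 78 is 1 array, assumed to vary like the other clones. Then 0 genes passed in limma (841 at an unadjusted p below 0.05), with Rpl22l1 at 1.66, Wnt7b at -1.19 and Hnrnpd at 0.63. The count was 5 with the block, 268 without array b, 442 without array c and 6056 without array a. Camera called 8 lists higher at the preset correlation, each with an adjusted p = 0.181 with an estimated correlation. They were pluripotency (10 up and 1 down of 33), G2/M (5 and 1 of 15), hypoxia (5 and 0 of 12), unfolded protein response (4 and 1 of 18), lysosome (7 and 2 of 18), DNA replication (6 and 4 of 22), glycolysis (5 and 0 of 16) and mitochondrial respiratory chain (8 and 4 of 28). The pluripotency median went from 0.27 to -0.04 with the block and the 2 arrays left out, and those of the last 3 lists fell below the median of all genes with scaling. Adjusted over the list alone the counts were 10 and 1, 5 and 1, 5 and 0, 4 and 1, 8 and 2, 6 and 4, 5 and 0, and 8 and 4.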

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

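The tests on the higher-signal arrays, on the share of X-linked genes and on the sex of the clone were chosen after the shift of X-linked genes was seen. For the mean level of each of 117 genes, gene lists and chromosome medians over the 4 clones, 1 clone stood apart from the other 3 by Dixon's test in 6 cases. Chance gives about 1 in 20, or 5.85 of 117, so the number of cases is no more than chance would give.

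In clone 70 against the mean of the other clones, the median change of X-linked genes lay 0.573 above that of autosomal genes. It lay 0.359 above on log2 values without normexp. The same measure was -0.216 to -0.162 for the other clones, whose reference means hold clone 70. Among the lower-signal arrays of JM8, IDG3.2 and clones 48 and 64, without clone 70, it was 0.034 for clone 48 and 0.041 for clone 64. The signal level of the arrays was argued against by the 6 higher-signal arrays alone, which gave 0.538 (95% bootstrap interval over genes 0.494 to 0.577). A few strongly raised families were argued against by 88.3% of the 308 genes lying above the autosomal median, and probe brightness by 4 groups of 77 genes from dim to bright, at 0.434, 0.598, 0.792 and 0.586 against autosomal genes of like brightness. The sex of clone 70, the 1 clone labelled female, stays open as a biological hypothesis that may account for the 0.573, because with 1 female clone sex and clone cannot be told apart.

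The other values that stood apart are given without explanation. Dppa5a was at 14.66 in clone 78 and at 14.47 to 14.49 in the other clones. Quantile normalization gave it the same value on all 3 arrays of clone 78, so this is a difference in rank among the brightest probes. Myc was at 5.80 in clone 64 and at 5.56 to 5.60 in the others, detected on 2 of the 3 arrays of clone 64 and on 0 of 3 in each other clone. Its difference thus rests on values not above background. Usp18 was at 7.72 in clone 48 and at 5.08 to 5.25 in the others. Phlda2 was at 8.05 in clone 70 and at 9.98 to 10.25 in the others. The median level of two-cell-stage transcripts was 6.41 in clone 70 and 5.28 to 5.38 in the others.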

How the results depend on the processing

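The settings that leave out the 2 high-background arrays, use signal level as a block, or use the lower-signal or higher-signal arrays only were chosen after seeing the data. Of 246 gene values named, none changed direction with a call under any setting. Log2 values without normexp ended 3 calls, scaling 7, the values of the series matrix 6, no detection filter 2, detection on every array 1 and no trend 4, the block ended 51, the block without the high-background arrays 42 and their removal alone 17. Where no cause is given, the cause was not tested. Signal over background limits what can be seen on the 2 high-background arrays, and the single MEF array gives no spread of its own. Slide as a block was not run, because the files used here name no slides. Removing the detection filter, testing each probe on its own, ignoring clones and a random block per line moved no total by over 1.5 times. Without the filter clone 78 had 2082 genes higher and 2300 lower and clone 70 675 and 413.

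Log2 values without normexp gave 1 gene for clone 64 and a mean position of the clones of 1.14 between MEF and IDG3.2. Scaling gave 6 genes for clone 64 and 2561 for clone 70. The series' value table gave 0 for clone 64 (747 at an unadjusted p below 0.05 in limma), a mean position of 1.07 and JM8 at 1.09 between MEF and IDG3.2, and a difference of at least 1 in log2 gave 1.07. Detection on every array, with fewer genes tested, gave 1162 for iPSC against MEF, 843 for ESC against MEF, 2371 among the clones, 1825 for clone 48 (861 higher), 0 for clone 64 (399 unadjusted), 900 for clone 70 (437 higher) and 1577 for clone 78 (792 higher). No trend gave 1 for clone 64. A 2-fold minimum gave 2829 among the clones, 983 for clone 48, 367 for clone 70 and 973 for clone 78. Each line as its own group gave 4869, 3725 and 664 for iPSC against MEF, ESC against MEF and iPSC against ESC. Estimated correlation left 0 gene lists in camera for each of the 7 comparisons, against 15, 15, 7, 13, 6, 11 and 8 at the preset one.

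Without the 2 high-background arrays, with fewer arrays, ESC against MEF gave 2582, clone 70 2510 and clone 78, with 1 array left and assumed to vary like the other clones, 0 (841 unadjusted). Signal level as a block gave 3657 for iPSC against MEF, 3969 for ESC against MEF, 634 among the clones, 7 for clone 48, 338 for clone 70 and 5 for clone 78. Both together gave 5632, 6007 and 134 for iPSC against MEF, ESC against MEF and iPSC against ESC, 1179 among the clones, 65 for clone 48, 116 and 10 gene lists for clone 64, and 0 for clone 78 (738 unadjusted). The higher-signal arrays alone gave 829 among the clones. In the comparisons of cell types, each fit with the block took each line as its own group.

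With 1 line or array left out, iPSC against MEF gave 1418 (without clone 64) to 2968 (without clone 48), ESC against MEF 680 (without JM8) to 1892 (without IDG3.2) and 913 without clone 64, and iPSC against ESC 0 throughout (294 to 1502 unadjusted). The F test gave 3207 (without clone 78 array b) to 7401 (without clone 78 array a). Clone 48 gave 2011 (its array c) to 5306 (clone 78 array a), clone 64 0 (its array a or b) to 1163 (clone 78 array a), clone 70 525 (its array c) to 3418 (clone 78 array a) and clone 78 268 (its array b) to 6056 (its array a). The X-linked shift of clone 70 ran from 0.568 to 0.583, and was 0.359 without normexp, 0.617 with the series' value table, 0.571 without the high-background arrays, 0.574 with the block and 0.541 with both.

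The replicate numbers of the labels do not pair the samples. Of 18 same-number pairs across clones, with r from -0.233 to 0.128, 2 were over 0.1, and 3 of 12 samples correlated best with their own number. With the replicate block on the series' value table the F test called 4352 genes against 4910 without, clone 48 3106 against 3393, clone 64 0 against 0 (in limma), clone 70 1205 against 1419 and clone 78 3752 against 4048.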

Other observations

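The tests of strain and of chromosome dose in JM8 and of line-specific expression in IDG3.2 were chosen after the results were seen. The ESC lines, with 1 array each and so no test, differed from each other by at least 2-fold in 546 genes higher in JM8 and 784 higher in IDG3.2, of 8745 detected in either. Genes of the primitive streak and epiblast were among the largest differences towards IDG3.2. So were Actg2 (at least 25.2-fold), Mmp13 (at least 17.1-fold) and Tagln (at least 8.40-fold), undetected in JM8 and at 13.47, 8.27 and 11.00 in MEF. Fgf8 was at least 23.5-fold higher in IDG3.2 and Fgf5, a marker of the primed epiblast, at least 21.2-fold, both undetected in JM8. The Wnt target Sp5 differed by -5.06 (JM8 minus IDG3.2, log2), the organizer gene Gsc by -4.17 and Krt8 by -3.96, and Lhx1, Mixl1 and Evx1 were undetected in JM8 and at least 6.52-fold, 6.18-fold and 8.59-fold higher in IDG3.2. In the other direction Gstp2 was higher in JM8 by 3.55 and Aire, a regulator of self-antigen expression, by 3.41, and Myo1f and Tex14, a germ cell bridge protein, were at least 7.66-fold and 9.94-fold higher. These genes were chosen after their values were seen.

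The mesoderm and primitive streak list had a median of -1.68 and primed pluripotency -1.05, both below all of 10000 random lists of like expression, and germline genes 0.88 and core pluripotency 0.57, both above all of them. The random lists were drawn as if genes were independent. Members of a list can vary together, so these placements are not p-values and do not measure the strength of evidence. In JM8 81.8% of pluripotency genes, 77.8% of germline genes and 14.3% of mesoderm genes were higher. Scaling gave -1.33, -0.91, 0.63 and 0.58, and log2 values without normexp -0.72, -0.48, 0.40 and 0.55. Endoderm genes lay at -0.77 and Hox genes at -0.35, while epithelial (-0.08), trophoblast (-0.08) and lysosome genes (0.00) lay near 0. Eif2s3y was undetected in JM8 (5.03) and at 9.06 in IDG3.2 and 7.94 in MEF, and both lines were labelled male.

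Chromosome 8 stood out in JM8, whose 518 genes there lay 0.248 (95% bootstrap interval over genes 0.214 to 0.286) above the mean of IDG3.2 and the lower-signal arrays of clones 48 and 64, relative to autosomal genes, with 71.4% of them above and genes such as Nqo1 (1.88) and Mt2 (1.96). The strain of JM8 as the whole cause was argued against by the other autosomes, of which none shifted by more than 0.0900 in size (chromosome 18, 95% bootstrap interval of its shift -0.166 to -0.0103, short of the 0.214 at the lower end for chromosome 8), and a local cluster by 3 equal stretches of the chromosome in gene order, at 0.206, 0.320 and 0.230. Against autosomal genes of like brightness, the dimmest of 4 groups of chromosome 8 genes gave 0.028 and the others 0.257, 0.320 and 0.293. The prediction written before the test asked for a shift in each group, which the dimmest did not show, so the test did not decide on brightness. How its outcome is read was corrected after the result was seen. The shift remained in the brighter groups, and brightness stays open as an explanation. An extra dose of chromosome 8 in this culture is a candidate explanation that stays undecided, as 1 array and no DNA measurement bear on it. The shift was 0.160 without normexp and 0.213 with scaling, and in the series' value table, against IDG3.2 and clone 48 only, 0.276.

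Fibroblast and matrix genes were higher in IDG3.2 than in JM8 by a list median of 1.69 (39 genes). Normalization was argued against by the other scales, the lowest of which gave 1.04. As a hypothesis, MEF-like cells making up 1 share of the IDG3.2 culture would give each gene about the same share of the MEF signal, and over 37 genes this share was 12.3% in the median with a quartile ratio of 2.61, within the limit set before the test, although Col5a2 (-1.19%), Col3a1 (1.09%), Pdgfrb (1.97%), Col1a2 (2.21%), Col6a2 (3.56%) and Col1a1 (4.29%) lay far below it and Acta2 (72.9%) above, so 1 share does not describe every gene. Macrophage and blood genes held 3.77% (6 genes), interferon-stimulated genes 5.64% (9) and Hox genes 6.88% (10) of the MEF signal. Expression of these genes by the line itself stays open, since 1 array cannot separate the 1.69 from the culture, and this applies to each position of IDG3.2 between MEF and JM8 given above.

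Other splits of the 12 iPSC arrays into groups of the same sizes, 100 drawn with the real one counted, were run for each count of genes among the clones. For the F test over the clones 1 split, the real one, called 5051, and the highest other 1058. For clone 48 1 split called 3516 and the highest other, 1443, set 3 of the 4 lower-signal arrays apart. No other drawn split thus reached the count of the F test or that of clone 48. Arrays of a clone mostly share a signal level, so the splits cannot tell clone from signal level. With the block 634 and 7 genes were left. For clone 78 1 split called 4014, with 229 in the highest other, so no other drawn split reached its count. The splits cannot tell this clone from signal level and background either, and 5 genes were left with the block. For clone 64 4 of the 100 splits called at least 3. The other 3 of them, the highest with 2651, all set apart the 2 high-background arrays and clone 64 array b, which points to a structure of the samples, and as the median of the other splits was 0 and the count itself fell to 0 or 1 in several settings, chance is not taken as excluded for a count of 3. For clone 70 5 of 100 splits called at least 1531. The highest others, 2046, 1955 and 1679, set apart the 3 arrays of clone 48 or of clone 78. As these are clones themselves, the splits cannot decide on chance for that count, which was not excluded. The count was 338 with the block and 1445 within the higher-signal arrays.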
